A study of Yarrowia lipolytica with 9 samples.

How the data were processed

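The series holds 9 RNA-seq libraries of the yeast *Yarrowia lipolytica* strain W29. Cells grew in bioreactors whose medium was kept at pH 2.0, 4.0 or 6.0, with 3 bioreactors per pH, and were taken at hour 50. Per the labels' protocols, total RNA was extracted with glass-bead homogenization, treated with DNase and cleaned on columns. Strand-specific libraries were then made with Illumina's TruSeq kit, pooled, and read for 101 cycles on an Illumina HiSeq instrument. Per the submitters' processing notes, bcl2fastq 1.8.4, Trimmomatic 0.30, TopHat2 2.0.10, HTSeq and edgeR were used; the role and settings of each, the genome build, the annotation and any filter on low genes are not given in the sources used here. Whether HTSeq counted by strand is not given either, so values of overlapping, antisense or near-identical genes are uncertain.

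The deposited table has 6170 rows, 1 per gene identifier, and 1 column per library. Per the file headers, its values are a normalized signal: reads per gene in CPM (counts per 1e+06 reads), which the authors divided by the effective library size of edgeR. Such a value is comparable between libraries and need not sum to the same total in each. The column sums lay between 904216 and 910806 at pH 2.0, 1010486 and 1094635 at pH 4.0, and 1051586 and 1056851 at pH 6.0. All values (100% in each library, tolerance 0.01 reads) were whole multiples of the worth of 1 read, which was 0.0563 to 0.0779 CPM. The whole reads recovered in this way came to 12974822 to 17701766 per library, and 3 reads, taken as the floor, corresponded to 0.169 to 0.234 CPM. The ratio of effective library size to recovered reads was 1.10 to 1.11 at pH 2.0, 0.914 to 0.990 at pH 4.0 and 0.946 to 0.951 at pH 6.0. Trimmed-mean (TMM) factors recomputed from the recovered reads had the same values to 3 significant digits, so the deposited scaling is a TMM scaling of these rows.

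The identifiers are YALI0 locus tags. The reference table given for this series, with 8689 genes of a W29/CLIB89 assembly under other locus tags and without descriptions, matched 0 of them, so neither the data nor that table pairs the identifiers with names, and no coordinates are given. Functions are stated in words as background, from general knowledge of published locus-tag assignments. They were written down, with the gene lists, before the data were examined. Of 28 lists fixed then, 14 had locus tags of this kind and could be used; 61 of their 62 loci were measured, no locus was on more than 1 list, and 7 lists had the 3 measured members needed for a test. The other 14 lists were to be filled from descriptions and stayed empty. A set of 48 key loci, 47 of them measured, was fixed in the same way; together, lists and key loci make 63 measured loci. The alkaline extracellular protease YALI0F31889g is the locus without a row here.

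Genes with at least 1 CPM in at least 3 of the 9 libraries were kept (6165; 5 removed). Values were tested as log2(CPM + 1), so that log2 fold changes of low genes are understated. The test was limma (version 3.58.1, R 4.3.3) with a mean-variance trend, in 1 fit over the 9 libraries with 1 mean per pH, so that the groups share 1 estimate of the spread (6 residual degrees of freedom). Adjusted p-values are Benjamini-Hochberg values over the 6165 genes, two-sided, and a gene was called at an adjusted p under 0.05. The 3 pairwise differences, a moderated F test over the 3 pH values, and a contrast of the 2 steps (pH 4.0 to 6.0 minus pH 2.0 to 4.0) were tested. The design planned for a table of CPM was used as written. Lists were tested with camera in limma with a preset correlation of 0.01 between genes, adjusted over the 7 lists of a comparison, and again with an estimated correlation. A count "adjusted over the list alone" applies the Benjamini-Hochberg step to the members of 1 list.

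Groups, tests, lists and alternatives were fixed before the data were examined, as was the rule for naming genes: the extremes of log2 fold change among called genes whose groups do not overlap and whose higher mean is at least 10 CPM (8 each way for pH 6.0 against 2.0, 5 each way for the others), up to 3 called members per list with the smallest adjusted p, and the key loci. Because the extremes have no descriptions, only the first 2 in each direction are printed. Uncalled values are treated as having no direction. Alternatives were pseudocounts of 0.25 and 5, no filter, a filter at 10 CPM, TMM factors of the deposited values, quantile normalization, a replicate block, no trend, a fit of the 2 groups compared, edgeR's quasi-likelihood test (4.0.16) and DESeq2 (1.42.0) on the recovered reads, leaving out each library, a stricter adjusted p of 0.01, and an absolute log2 fold change of at least 1. Scaling to equal totals was added after the column sums had been seen.

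Replicates of a group were not copies of 1 library: the chi-square of their recovered reads was 8.79 to 55.3 per degree of freedom, and their log2 values correlated at r = 0.986 to 0.998 across genes, which are not independent replicates. The code was tested on simulated counts drawn around each gene's mean over the 9 libraries, with changes planted at pH 6.0 (6148 genes). For pH 6.0 against 2.0 it recovered 91% of 100 genes changed by 1 on the log2 scale and 52% of 100 changed by 0.5, with 7 false calls among 156. The 156 include called members of a separate list of 10 genes that was also shifted by 0.5. Changed genes were few next to the 6148 and almost balanced in direction. The simulation therefore does not show the error rate where most genes change or where the scaling differs between groups.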

Results

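*Yarrowia lipolytica* is an oil-storing yeast that secretes citric acid, and the study asked how the acidity of the medium bears on citric acid and lipid production. The libraries profile the mRNA of strain W29, a wild-type isolate, at hour 50 of bioreactor cultures held at pH 2.0, 4.0 or 6.0, with 3 libraries per pH. The medium had 50 g/L glucose and 1 g/L ammonium sulfate, besides 1.5 g/L yeast extract and 1.7 g/L yeast nitrogen base. The labels describe bioreactors run in triplicate, so the libraries of a group are taken as separate cultures. Depth was 12974822 to 17701766 recovered reads per library.

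The 3 pH values separated on the first 2 principal components, which held 71.6% and 19.3% of the variance. Scores on the first component ran from -47.6 to -37.0 at pH 2.0, from 1.45 to 6.12 at pH 4.0 and from 36.2 to 37.5 at pH 6.0. Within pH 2.0, replicate A lay apart from replicates B and C, at -47.6 against -37.0 and -37.9. The F test of limma called 5177 of 6165 genes (84.0%) as differing among the 3 pH values.

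**Figure D1:**
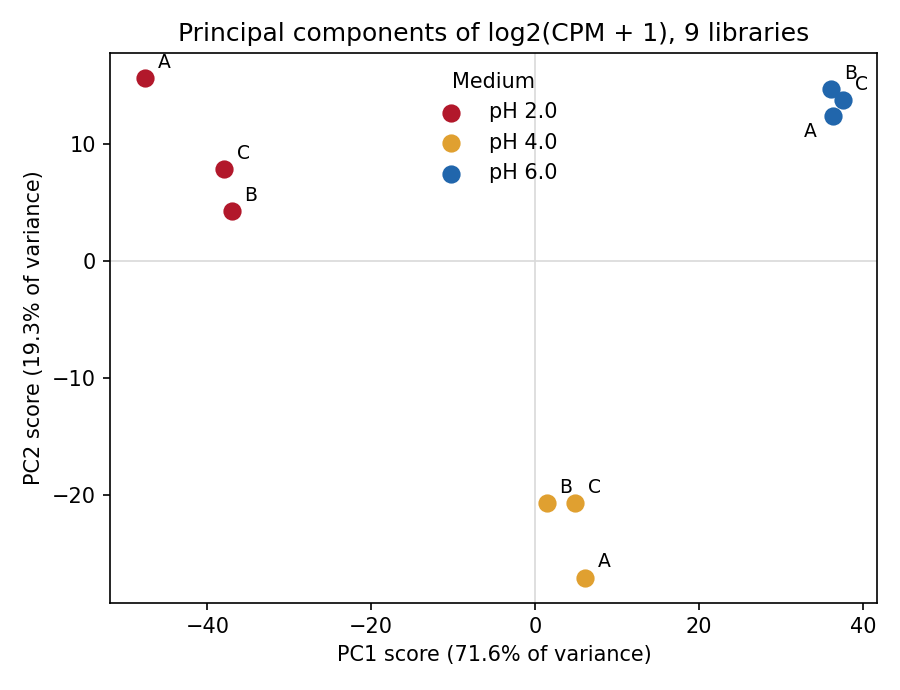
Scores of the 9 libraries on the first (horizontal) and second (vertical) principal components of log2(CPM + 1), coloured by medium pH and lettered by replicate. The first component holds 71.6% of the variance and orders the groups by pH; the second, with 19.3%, sets the pH 4.0 libraries, at -27.1 to -20.7, below all the others.

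Between pH 2.0 and pH 6.0, transcripts of the citrate exporter, Rim101, the acid extracellular protease and the 5 listed pentose phosphate and polyol genes were higher at pH 6.0. Those of 2 acyl-CoA oxidases and 1 alkane cytochrome P450 were lower, while the oxidase YALI0C23859g was higher. The other listed oxidases were not called under the deposited scaling. The citrate exporter YALI0D20196g, a plasma membrane carrier of citrate, rose from 501 ± 101 CPM at pH 2.0 to 2933 ± 191 CPM at pH 6.0 (SD, n = 3 each; log2 fold change 2.56, SE 0.20, adjusted p = 1.54e-06). Rim101, the transcription factor of the ambient pH response (YALI0B13640g), rose from 181 ± 3.16 to 738 ± 45.8 CPM (log2 2.02, SE 0.07, adjusted p = 4.60e-09). The acid extracellular protease YALI0B05654g went from 8.98 ± 2.52 to 657 ± 151 CPM (log2 6.05, SE 0.25, adjusted p = 2.01e-08). The plasma membrane proton ATPase YALI0B22682g, which pumps protons out of the cell, rose by a smaller amount, from 121 ± 9.77 to 184 ± 6.27 CPM (log2 0.60, adjusted p = 2.95e-05).

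**Figure D2:**
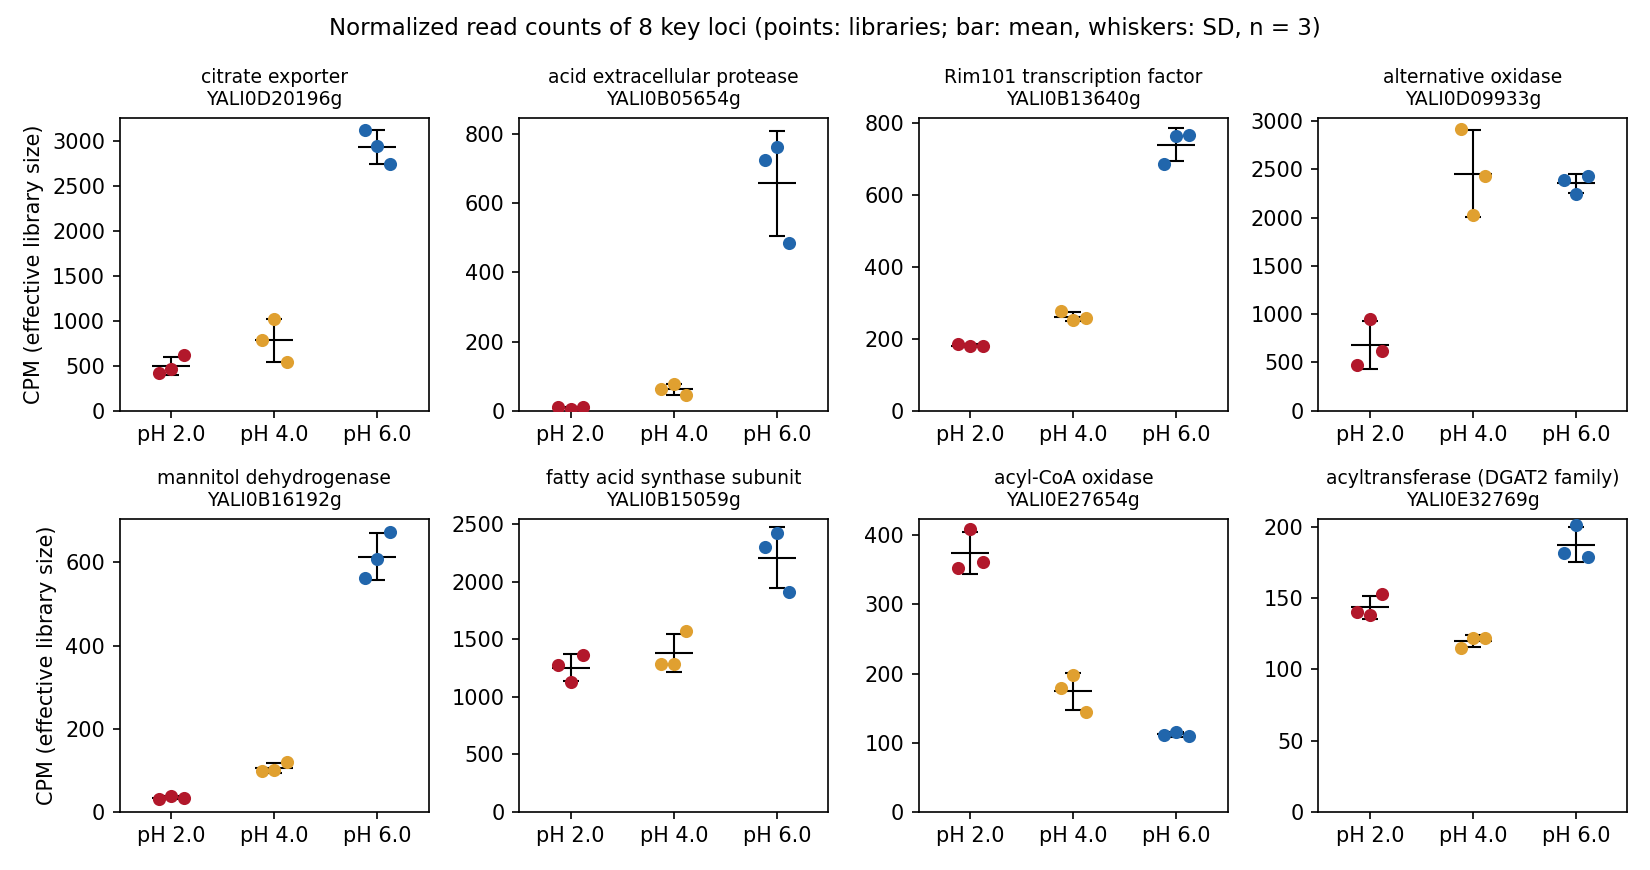
CPM (vertical axis, from 0, normalized to effective library size) of 8 listed or key loci in each library by medium pH. Mannitol dehydrogenase YALI0B16192g is a list member and not a key locus. Points are libraries, bars are means and whiskers are SDs (n = 3). The citrate exporter rises mainly above pH 4.0 (means 501, 782 and 2933 CPM), whereas the alternative oxidase rises below it (681, 2456 and 2354 CPM).

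The pentose phosphate pathway makes NADPH and pentoses, and polyol enzymes handle sugar alcohols. All 5 members of this list rose from pH 2.0 to pH 6.0, also when adjusted over the list alone. Glucose-6-phosphate dehydrogenase (YALI0E22649g), its entry step, rose by 1.04 on the log2 scale (SE 0.09), 6-phosphogluconate dehydrogenase (YALI0B15598g) by 0.66 (SE 0.08), and mannitol dehydrogenase (YALI0B16192g) from 34.1 ± 3.58 to 614 ± 56.0 CPM (log2 4.13, SE 0.11, adjusted p = 7.99e-10). Camera called the list as higher (adjusted p = 0.0108). With an estimated correlation the call was lost (adjusted p = 0.647), as it was under quantile normalization (adjusted p = 0.0582).

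Of 10 genes of fatty acid synthesis and desaturation, 6 were higher at pH 6.0, 1 was lower and 3 were not called, with 7 called when adjusted over the list alone. Both fatty acid synthase subunits rose, YALI0B15059g from 1254 ± 120 to 2210 ± 269 CPM (log2 0.81, SE 0.12) and YALI0B19382g from 694 ± 69.0 to 1192 ± 81.2 CPM (log2 0.78, SE 0.10). The delta-12 desaturase YALI0B10153g, which makes linoleic acid, rose by 0.95 on the log2 scale (SE 0.12), and malic enzyme YALI0E18634g by 0.72 (SE 0.09). Acetyl-CoA carboxylase YALI0C11407g rose by 0.31 (SE 0.09), but that call was lost under total scaling (0.09) and quantile normalization (0.02). The delta-9 desaturase YALI0C05951g was not called (log2 0.04). The 2 subunits of ATP-citrate lyase, which makes cytosolic acetyl-CoA from citrate, had log2 fold changes of -0.08 (YALI0E34793g) and -0.19 (YALI0D24431g) and were not called; under total scaling both were called lower (-0.29 and -0.41). The list as a whole was not called (adjusted p = 0.357), and under total scaling its members split into 4 higher and 3 lower.

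Of 10 genes of triacylglycerol and phospholipid synthesis, 5 were higher at pH 6.0 and 1 was lower (6 adjusted over the list alone; list test, adjusted p = 0.581). Glycerol-3-phosphate acyltransferase (YALI0C00209g), the first acylation step, rose from 267 ± 18.5 to 549 ± 58.4 CPM (log2 1.04, SE 0.12), and lysophosphatidate acyltransferase (YALI0E18964g), the next, by 0.57 (SE 0.07). The diacylglycerol acyltransferases, which complete triacylglycerol, went opposite ways: the DGAT2-family enzyme YALI0E32769g had a log2 fold change of 0.38 (SE 0.07) and the DGAT1-family enzyme YALI0D07986g one of -0.30 (SE 0.09). The call of the former was lost under total scaling (log2 0.17) and quantile normalization (log2 0.18). Phosphatidate phosphatase YALI0D27016g rose by 0.34 (SE 0.07), a call also lost under total scaling (0.12) and quantile normalization (0.0060). The sterol acyltransferase YALI0F06578g was not called (log2 -0.23), but was called lower under total scaling (-0.45). Under total scaling 3 members of the list were higher and 5 lower. Among 3 lipases, 1 was higher and 2 were lower, also when adjusted over the list alone (list test, adjusted p = 0.937; median log2 -0.20, mean 0.07, tested direction up). The lipid body lipase YALI0D17534g was the higher one (log2 0.86, SE 0.07, adjusted p = 1.40e-06). The lower call of YALI0F10010g (log2 -0.20) was lost with the replicate block, without the trend, with DESeq2 and in some fits without single libraries. That of the extracellular lipase YALI0A20350g (7.24 to 5.02 CPM) was lost under quantile normalization (log2 -0.05) and without pH 6.0 replicate C.

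Of 9 genes of beta-oxidation and the peroxisome, 2 were higher, 4 lower and 3 not called (6 called when adjusted over the list alone; list test, adjusted p = 0.770); under total scaling 2 were higher and 6 lower. The acyl-CoA oxidases, which open each round of beta-oxidation, included YALI0E27654g, which fell from 374 ± 30.2 to 112 ± 2.98 CPM (log2 -1.73, SE 0.11), YALI0E06567g, which fell by 1.20 on the log2 scale (SE 0.10), and YALI0C23859g, which rose by 1.35 (SE 0.14). The oxidases YALI0F10857g (log2 0.11), YALI0D24750g (-0.04) and YALI0E32835g (-0.16) were not called. Under total scaling YALI0D24750g (-0.25) and YALI0E32835g (-0.37) were called lower, the former also under quantile normalization (-0.31). The multifunctional enzyme YALI0E15378g of the same pathway rose by 0.87 (SE 0.09), while peroxisomal thiolase YALI0E18568g, its last step, fell by 0.55 (SE 0.12). The alkane cytochrome P450 YALI0E25982g dropped from 6652 ± 355 to 2471 ± 123 CPM (log2 -1.43, SE 0.13, adjusted p = 3.84e-06).

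Of 11 genes of the TCA and glyoxylate cycles and anaplerosis, 4 were higher at pH 6.0, 3 lower and 4 not called (7 called when adjusted over the list alone; list test, adjusted p = 0.803). Aconitase (YALI0D09361g) rose by 0.43 (SE 0.08) and malate synthase (YALI0D19140g), a glyoxylate cycle enzyme, by 0.70 (SE 0.16). NADP-dependent isocitrate dehydrogenase (YALI0F04095g) fell by 0.46 (SE 0.09) and the citrate synthase YALI0E02684g by 0.38 (SE 0.08). Isocitrate lyase YALI0C16885g rose by 0.36 (SE 0.14). That call was lost under total scaling (0.14), under quantile normalization (0.12) and in some fits without single libraries. The citrate synthase YALI0E00638g was not called (log2 -0.20), but was called lower under total scaling (-0.42). Under total scaling 2 members of this list were higher and 5 lower. In glycolysis 2 of 4 genes were lower and none was higher (2 adjusted over the list alone; list test, adjusted p = 0.803), glucokinase YALI0E15488g falling by 0.35 (SE 0.08). The alternative oxidase YALI0D09933g, which passes electrons to oxygen without pumping protons, rose from 681 ± 245 to 2354 ± 101 CPM (log2 1.85, SE 0.21), and the external NADH dehydrogenase YALI0F25135g from 290 ± 39.0 to 965 ± 56.3 CPM (log2 1.74, SE 0.09). The 2 mitochondrial carriers of citrate, YALI0F26323g and YALI0B10736g, were not called, with log2 fold changes of 0.15 and 0.05. The zinc finger regulator of hyphal growth, YALI0B21582g, used as a marker of the filamentous cell form, was not called either (39.4 ± 3.52 and 34.9 ± 4.02 CPM, adjusted p = 0.346), but was called lower under total scaling (log2 -0.38). AMP deaminase YALI0E11495g, an enzyme of AMP breakdown that has been tied to the onset of lipid storage, was called lower (log2 -0.20, SE 0.08, adjusted p = 0.0386); that call was lost with DESeq2 and without pH 2.0 replicate B (-0.20) or C (-0.14) or pH 6.0 replicate A (-0.19), B (-0.19) or C (-0.22).

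Over all genes, 4498 of 6165 (73.0%) differed between pH 6.0 and pH 2.0, 2164 higher and 2334 lower, and 1298 of them by at least 1 on the log2 scale (595 higher, 703 lower). The 2 extremes in each direction have no description here. YALI0A00110g went from 6.62 to 4947 CPM (log2 9.36, SE 0.22) and YALI0B00374g from 53.1 to 6514 CPM (log2 7.10, SE 0.37). YALI0D19338g went from 3206 to 1.34 CPM (log2 -10.42, SE 0.15) and YALI0A13497g from 1771 ± 1572 to 4.42 ± 0.873 CPM (log2 -7.96, SE 0.52). The last depended on single libraries, with log2 -7.25 without pH 2.0 replicate A and -8.60 without replicate B. With a pseudocount of 5 the values were 8.74 for YALI0A00110g, -8.97 for YALI0D19338g and -7.16 for YALI0A13497g; in DESeq2 the last 2 were -11.18 and -8.61. Of the 63 listed and key loci, 29 were higher and 15 lower, with 44 called over these loci alone. Scaling to equal totals, which moves the median log2 fold change of all genes from -0.04 to -0.25, gave 1522 higher and 3006 lower genes, and 23 higher and 26 lower among the 63 loci.

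**Figure D3:**
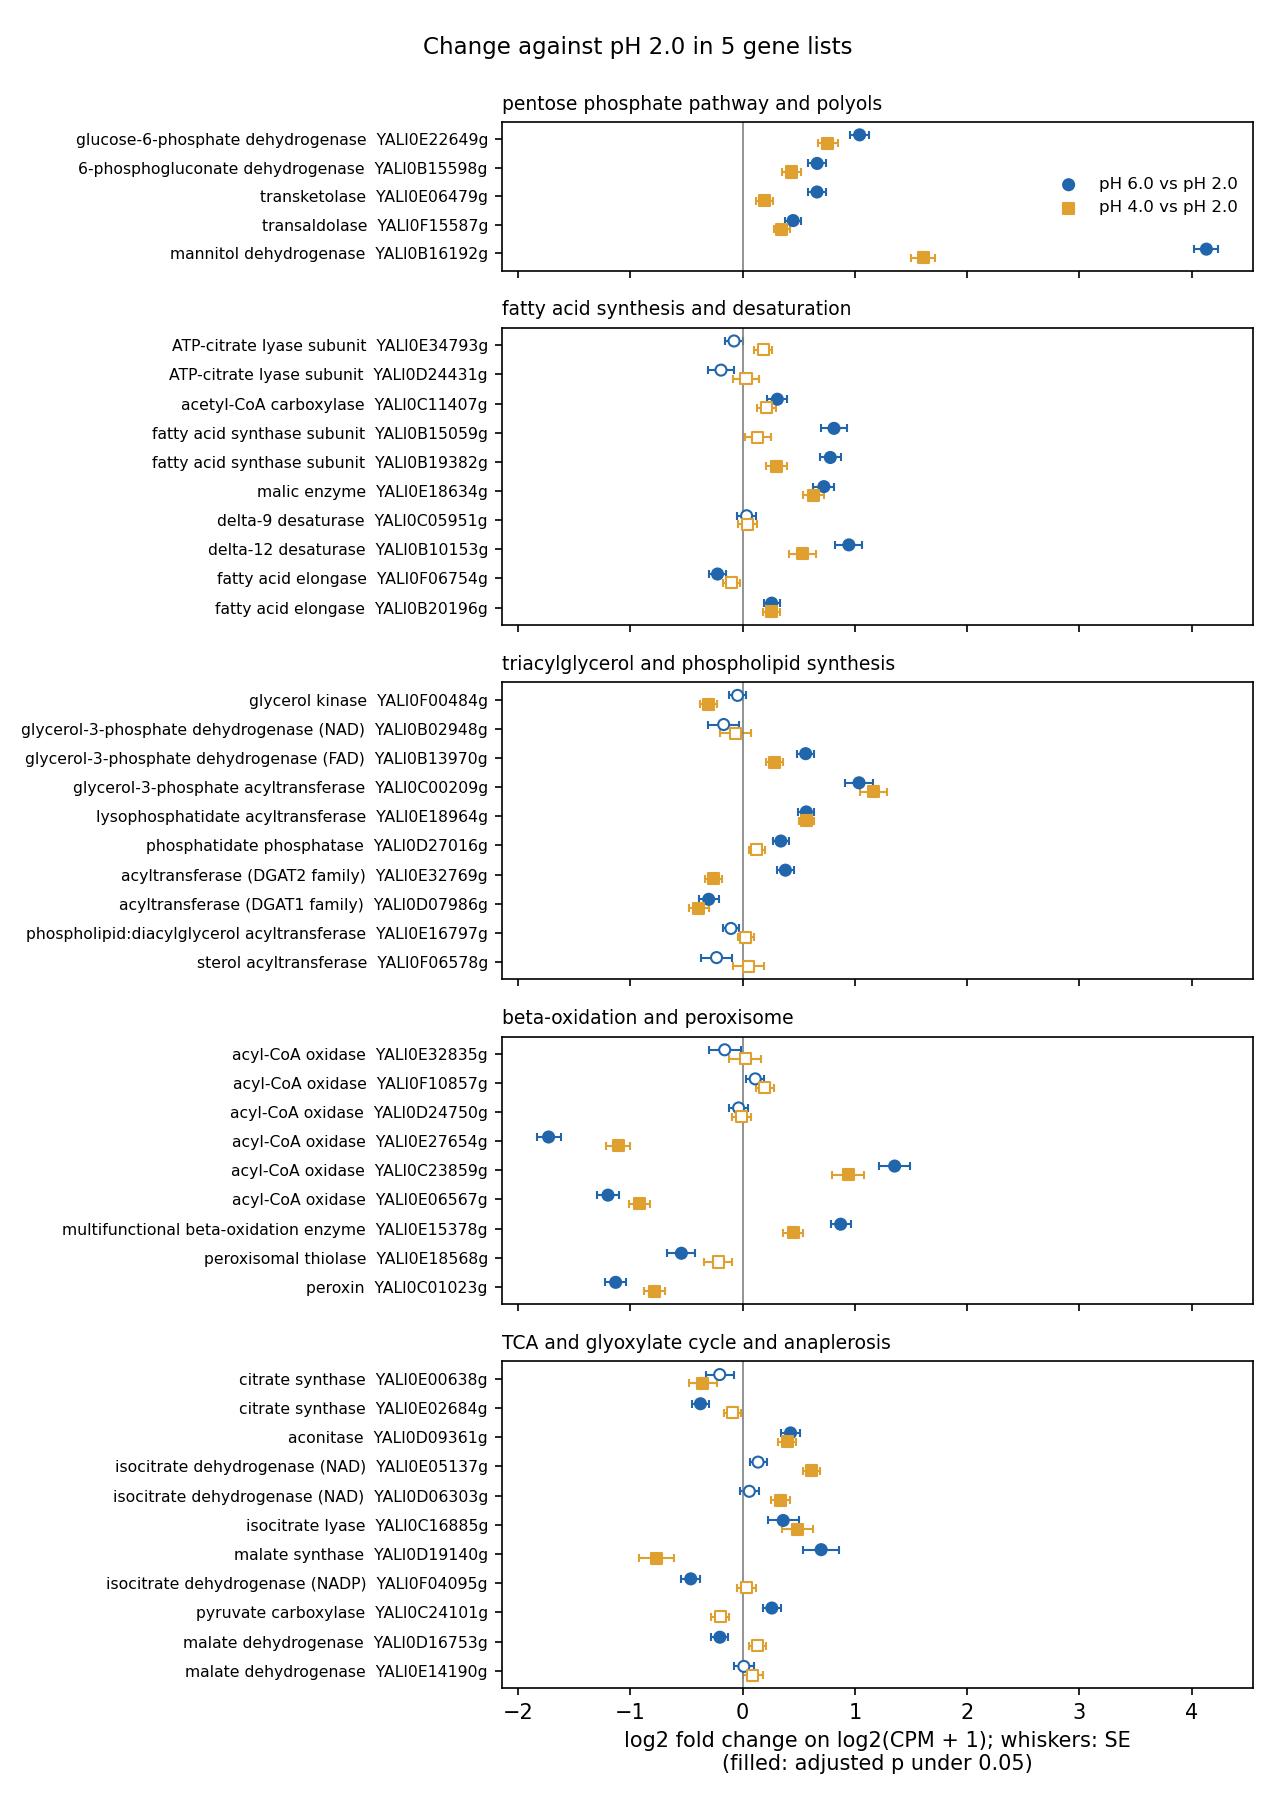
log2 fold changes (horizontal axis, on log2(CPM + 1); whiskers are SEs from limma) against pH 2.0 for the members of 5 gene lists; circles are pH 6.0, squares pH 4.0, and filled symbols have an adjusted p under 0.05. All 5 pentose phosphate and polyol genes lie right of 0 in both comparisons, transketolase at pH 4.0 turning to -0.01 under total scaling and transaldolase at pH 4.0 to -0.000836 under quantile normalization; members of the other lists lie on both sides.

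Between pH 2.0 and pH 4.0, transcripts of the alternative oxidase, the external NADH dehydrogenase, the first acylation steps of lipid synthesis, the acid protease and Rim101 rose. The alternative oxidase YALI0D09933g was at 2456 ± 446 CPM at pH 4.0 (log2 1.89, SE 0.21, adjusted p = 4.44e-05) and the external NADH dehydrogenase YALI0F25135g at 821 ± 20.3 CPM (log2 1.51, SE 0.09). Glycerol-3-phosphate acyltransferase YALI0C00209g stood at 605 ± 111 CPM (log2 1.17, SE 0.12) and lysophosphatidate acyltransferase YALI0E18964g rose by 0.57 (SE 0.07). The acid protease YALI0B05654g reached 61.4 ± 17.1 CPM (log2 2.64, SE 0.25) and Rim101 261 ± 12.8 CPM (log2 0.53, SE 0.07, adjusted p = 9.47e-05). The citrate exporter YALI0D20196g was at 782 ± 237 CPM (log2 0.61, SE 0.20, adjusted p = 0.0214); this call was lost under total scaling (log2 0.41), under quantile normalization (0.31), and without pH 2.0 replicate A (0.50) or B (0.58) or pH 4.0 replicate A (0.58) or B (0.40).

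The 5 pentose phosphate and polyol genes were called higher at pH 4.0 than at pH 2.0, also over the list alone, with mannitol dehydrogenase YALI0B16192g up by 1.61 (SE 0.11) and glucose-6-phosphate dehydrogenase YALI0E22649g by 0.76 (SE 0.09); under total scaling and under quantile normalization 3 of the 5 were called. The call of transketolase YALI0E06479g (log2 0.20, SE 0.08, adjusted p = 0.0416) was also lost with the replicate block (adjusted p = 0.0784), in a fit of the 2 groups compared (adjusted p = 0.0999), and without pH 2.0 replicate A (0.16) or B (0.18), pH 4.0 replicate A (0.17) or B (0.20), or pH 6.0 replicate A, B or C (0.20 each). Camera called the list (adjusted p = 0.0300; adjusted p = 0.810 with an estimated correlation, and 0.305 under quantile normalization). No other list was called. In fatty acid synthesis and desaturation 4 of 10 genes were higher and none lower (4 over the list alone; adjusted p = 0.255), among them malic enzyme YALI0E18634g (log2 0.63, SE 0.09) and the delta-12 desaturase YALI0B10153g (log2 0.53, SE 0.12); under total scaling 2 were higher and 1 lower. In triacylglycerol and phospholipid synthesis 3 were higher and 3 lower (6 over the list alone; adjusted p = 0.795; 2 higher and 4 lower under total scaling), both diacylglycerol acyltransferases being lower (YALI0E32769g log2 -0.26, SE 0.07; YALI0D07986g log2 -0.39, SE 0.09). Of the 3 lipases 1 was higher and 2 were lower (3 over the list alone, list test adjusted p = 0.795). The lower call of the extracellular lipase YALI0A20350g (log2 -0.46) was lost under quantile normalization (-0.05) and without pH 2.0 replicate A or pH 4.0 replicate B.

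In beta-oxidation and the peroxisome 2 genes were higher, 3 lower and 4 not called at pH 4.0 against pH 2.0 (6 over the list alone; adjusted p = 0.795; 2 higher and 5 lower under total scaling and under quantile normalization). The acyl-CoA oxidase YALI0E27654g fell by 1.11 on the log2 scale (SE 0.11) and the peroxin YALI0C01023g, a protein of peroxisome assembly, by 0.79 (SE 0.10), whereas the oxidase YALI0C23859g rose by 0.94 (SE 0.14). The alkane cytochrome P450 YALI0E25982g fell to 3309 ± 692 CPM (log2 -1.03, SE 0.13). The hyphal regulator YALI0B21582g, the marker of the filamentous cell form, was lower at pH 4.0 than at pH 2.0 (39.4 ± 3.52 CPM at pH 2.0; log2 -0.50, SE 0.16, adjusted p = 0.0181; -0.70 under total scaling). That call was lost under quantile normalization (log2 -0.34) and without pH 2.0 replicate C (-0.43), and the value was -0.30 without pH 4.0 replicate C. In the TCA and glyoxylate cycles 4 genes were higher and 2 lower (7 over the list alone; adjusted p = 0.795), with 2 higher and 4 lower under total scaling. The NAD-dependent isocitrate dehydrogenase subunit YALI0E05137g rose from 380 to 582 CPM (log2 0.61, SE 0.08), and malate synthase YALI0D19140g dropped from 14.9 ± 2.77 to 8.41 ± 1.82 CPM (log2 -0.77, SE 0.16). In glycolysis 1 of 4 genes was lower, hexokinase YALI0B22308g (log2 -0.29, SE 0.08; 1 over the list alone; adjusted p = 0.805).

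Over all genes, 3907 (63.4%) differed between pH 4.0 and pH 2.0, 1900 higher and 2007 lower, and 706 by at least 1 on the log2 scale (265 higher, 441 lower). YALI0B00374g (log2 5.41, SE 0.37) and YALI0B18986g (3.55, SE 0.18) rose most, and YALI0A13497g (-7.29, SE 0.52) and YALI0C06259g (-5.47, SE 0.33) fell most under the naming rule. For YALI0A13497g the value was -6.58 without pH 2.0 replicate A and -7.92 without replicate B. With a pseudocount of 5 it was 1.92 for YALI0B18986g and -4.07 for YALI0C06259g, and in DESeq2 5.21 and -6.43. Among the 63 listed and key loci 26 were higher and 14 lower (42 called over these loci alone). Scaling to equal totals moved the median of all genes from -0.02 to -0.22 and gave 1267 higher and 2873 lower genes, and 16 higher and 20 lower of the 63 loci.

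Between pH 4.0 and pH 6.0, the citrate exporter, the acid protease, Rim101, mannitol dehydrogenase and the fatty acid synthase subunits rose, and the isocitrate dehydrogenase genes YALI0E05137g and YALI0F04095g fell. The citrate exporter YALI0D20196g rose by 1.95 on the log2 scale (SE 0.20, adjusted p = 4.80e-05), the protease YALI0B05654g by 3.41 (SE 0.25) and Rim101 (YALI0B13640g) by 1.49 (SE 0.07). Mannitol dehydrogenase YALI0B16192g rose by 2.52 (SE 0.11) and transketolase YALI0E06479g by 0.46 (SE 0.08). The fatty acid synthase subunits YALI0B15059g and YALI0B19382g rose by 0.68 (SE 0.12) and 0.48 (SE 0.10). The DGAT2-family enzyme YALI0E32769g rose from 120 ± 4.15 to 187 ± 12.2 CPM (log2 0.64, SE 0.07, adjusted p = 8.08e-05).

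In the pentose phosphate and polyol list 4 of 5 genes were higher at pH 6.0 than at pH 4.0 (4 over the list alone), but camera did not call it (adjusted p = 0.0591; adjusted p = 0.709 with an estimated correlation). The calls of YALI0E22649g (log2 0.28) and YALI0B15598g (0.23) were lost in some fits without single libraries, at 0.24 to 0.29 and 0.18 to 0.26; that of YALI0B15598g was also lost under quantile normalization (0.17) and with the replicate block. The list was called with a pseudocount of 5 (0.0473), under quantile normalization (0.0367), and without pH 4.0 replicate A (0.0424) or pH 6.0 replicate A (0.0477). The other 6 lists were not called (adjusted p = 0.523 for each). In fatty acid synthesis and desaturation 3 genes were higher and 1 lower (4 over the list alone), and in triacylglycerol and phospholipid synthesis 4 were higher and none lower (4 over the list alone; 2 higher and 1 lower under quantile normalization). In beta-oxidation and the peroxisome 2 were higher and 4 lower (6 over the list alone), the oxidase YALI0E27654g falling by 0.62 (SE 0.11); under quantile normalization none was higher and 3 were lower. In the TCA and glyoxylate cycles 2 were higher and 5 lower (7 over the list alone; median log2 -0.13, mean 0.0030, tested direction down). Malate synthase YALI0D19140g rose by 1.47 (SE 0.16) and pyruvate carboxylase YALI0C24101g, which makes oxaloacetate, by 0.46 (SE 0.08), while the isocitrate dehydrogenase genes YALI0E05137g and YALI0F04095g fell by 0.47 (SE 0.08) and 0.50 (SE 0.09). In glycolysis 1 gene was lower, glucokinase YALI0E15488g (log2 -0.51, SE 0.08; 1 over the list alone), and of the lipases 1 was higher (1 over the list alone). The alternative oxidase YALI0D09933g (log2 -0.05, SE 0.21) and the hyphal regulator YALI0B21582g (log2 0.32, SE 0.16) were not called.

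Over all genes, 3177 (51.5%) differed between pH 6.0 and pH 4.0, 1584 higher and 1593 lower, and 339 by at least 1 on the log2 scale (205 higher, 134 lower). YALI0A00110g (log2 8.03, SE 0.22) and YALI0E22286g (7.39, SE 0.27) rose most, and YALI0D19338g (-8.20, SE 0.15) and YALI0F13959g (-5.95, SE 0.26) fell most under the naming rule. With a pseudocount of 5 these were 6.05 for YALI0E22286g, -6.76 for YALI0D19338g and -5.30 for YALI0F13959g; in DESeq2 the first 2 were 8.21 and -8.98. Among the 63 loci 20 were higher and 12 lower (32 called over these loci alone).

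The course over the 3 pH values was not even for many genes. The contrast of the upper step (pH 4.0 to 6.0) minus the lower step (pH 2.0 to 4.0) was called for 3108 genes in limma. By group means alone, pH 4.0 lay above both others for 1071 of them, below both for 1100 and between them for 937. A called difference from each was not required, so genes that were level over the upper or lower step are included. The alternative oxidase YALI0D09933g lay above both, yet limma did not call it between pH 4.0 and 6.0 (log2 -0.05, adjusted p = 0.871). The upper step was the larger one for the citrate exporter YALI0D20196g (difference of steps 1.33 on the log2 scale, SE 0.35, adjusted p = 0.0102; 0.85 without pH 4.0 replicate C), Rim101 (0.96, SE 0.12) and mannitol dehydrogenase YALI0B16192g (0.92, SE 0.19). The lower step was the larger one for the alternative oxidase YALI0D09933g (-1.94, SE 0.37, adjusted p = 0.00211), the external NADH dehydrogenase YALI0F25135g (-1.27, SE 0.16) and glycerol-3-phosphate acyltransferase YALI0C00209g (-1.30, SE 0.21). The NAD-dependent isocitrate dehydrogenase subunit YALI0E05137g was highest at pH 4.0 (380, 582 and 418 CPM; difference of steps -1.09, SE 0.13), although it was called lower at pH 6.0 than at pH 2.0 under quantile normalization (log2 -0.24). Malate synthase YALI0D19140g (14.9, 8.41 and 24.7 CPM; 2.23, SE 0.27) and the DGAT2-family enzyme YALI0E32769g (144, 120 and 187 CPM; 0.90, SE 0.13) were lowest at pH 4.0.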

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

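Scaling to equal totals was chosen after the data had been seen; the other alternatives were fixed before. The counts of called genes stayed within 1.5 times under every scaling, filter, pseudocount and tool: edgeR called 4510, 3915 and 3179 genes and DESeq2 4467, 3908 and 3233 for pH 6.0 against 2.0, 4.0 against 2.0 and 6.0 against 4.0. Which genes were called changed more with the scaling. Quantile normalization kept 81.9% of the calls for pH 6.0 against 2.0 and 77.8% for pH 4.0 against 2.0. These shares count calls of either sign. For pH 6.0 against 2.0, 3675 of the 3682 shared calls had the same sign, and the rest were called in the opposite direction. Total scaling kept 85.7% and 83.8%. Counts for single libraries and stricter cutoffs follow. Leaving out each library in turn gave 4127 to 4596, 3577 to 3843 and 2639 to 3360, with 2282 to 3060 genes for unequal steps and 4900 to 5185 for the F test. A minimum absolute log2 fold change of 1 left 1298, 706 and 339 genes, and 1031 for unequal steps, by construction; an adjusted p under 0.01 left 1955 for unequal steps. The replicate block gave 4430, 3853 and 3106 genes. Libraries with the same letter had correlated deviations of r = -0.20 to 0.27, over 0.1 in 3 of 9 pairs, and the best match had the same letter in 5 of 18 cases, so the letters were not taken as pairs. Of the 7 lists, the 1 called for pH 6.0 against 2.0 and the 1 called for pH 4.0 against 2.0 became 0 under quantile normalization and with an estimated correlation. The 0 for pH 6.0 against 4.0 became 1 with a pseudocount of 5 and under quantile normalization, and 0 to 1 when single libraries were left out; the cause was not tested. The list alternative without shared members was not run, since no locus is on 2 lists.

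Of 5889 comparisons of a named gene's result with an alternative, 5553 counted as the same, 230 lost the call and 93 gained it. In the other 13 the sign changed, with a call under the deposited scaling or under the alternative. Results called under neither counted as the same whatever their sign, so sign changes among them are not in the 13. Of 174 called results, 122 kept direction and call throughout. Of the 13, 9 had no call under the deposited scaling, and so no direction, and were called lower under the alternative; the other 4 (YALI0E06479g, YALI0F15587g, YALI0B13970g and YALI0B22682g) were called and lost the call. Under quantile normalization the log2 fold changes of other sign for pH 6.0 against 2.0 were -0.24 (YALI0E05137g), -0.30 (YALI0D06303g) and -0.29 (YALI0E14190g). For pH 4.0 against 2.0 they were -0.17 (YALI0E15488g), -0.000836 (YALI0F15587g), -0.24 (YALI0F04095g), -0.30 (YALI0E14190g), -0.0485 (YALI0B13970g) and -0.27 (YALI0E16797g). Under total scaling they were -0.21 (YALI0E14190g, pH 6.0 against 2.0) and, for pH 4.0 against 2.0, -0.00983 (YALI0E06479g), -0.18 (YALI0E16797g) and -0.00152 (YALI0B22682g); the cause was not tested.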

Other observations

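The mitochondrial and pH 2.0 patterns below, and the tests of RNA carry-over, were chosen only after the data had been seen. Identifiers beginning with YalifM (16) are taken, from general knowledge, as genes of the mitochondrial genome. Of these, 13 were lower at pH 6.0 than at pH 2.0, with a median log2 fold change of -1.32 (range -1.50 to -0.44), 14 were lower at pH 6.0 than at pH 4.0 (median -1.30), and 0 were lower at pH 4.0 than at pH 2.0 (median 0.07). Their summed signal was 2323 ± 1195 CPM at pH 2.0, 2259 ± 541 at pH 4.0 and 777 ± 194 at pH 6.0 (SD, n = 3 each). Without pH 2.0 replicate A, 12 were lower at pH 6.0 than at pH 2.0, with a median of -0.92.

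Mitochondrial RNA and the RNA of 26 nuclear identifiers with the suffix r, taken as structural RNA, could both vary with the carry-over of RNA without poly(A) tails. Within groups, the mean deviations of the 2 sets correlated over the 9 libraries (r = 0.80, exact permutation p = 0.0139 over 216 permutations; rank correlation 0.917, p = 0.0139; r = 0.95 without the 2 farthest libraries), which leaves carry-over as an explanation of the differences between libraries of 1 pH. Between pH 6.0 and pH 2.0 the nuclear set had a median of -0.13 (8 higher, 5 lower) where the within-group slope of 0.199 predicts -0.26, and the median absolute deviation of its members was 0.256. The summed signal of the nuclear set went the other way, from 201 ± 27.4 CPM at pH 2.0 to 302 ± 45.4 CPM at pH 6.0, but 3 identifiers made up 96.7 of the rise of 100 CPM and members went both ways, so carry-over could not be told apart from an effect of pH.

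The 17 genes at least 3 on the log2 scale higher at pH 2.0 than at both other pH values varied most within pH 2.0. Their median coefficient of variation was 56.0% at pH 2.0, 25.3% at pH 4.0 and 20.3% at pH 6.0; replicate A was highest in 15 and replicate B lowest in 15, with a median ratio of A to B of 2.96. Of 10000 random lists of matched level, 0 reached the value at pH 2.0, so these genes varied more there than genes of like level. The 17 genes were picked from the same libraries by their pH 2.0 level, and 14 shared the order A, C, B. Genes that move together are not separate evidence, so the random lists cannot exclude noise as the source. No biological explanation of the differences within pH 2.0 was tested.

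The deposited values summed to less at pH 2.0: the log2 ratio of sums, pH 6.0 over pH 2.0, was 0.22. A few high genes did not account for this, with 0.22 left without the top 10 genes and 0.21 without the top 100, against 0.03 without the top 1000. Median log2 fold changes ran from -0.34 and -0.46 in the lowest and second-lowest of 10 bins of expression to 0.32 in the highest. Background reads spread evenly over genes and giving a middle bin its excess at pH 2.0 (5.22 CPM) would raise the lowest genes as much. The excess of the 100 lowest genes was 4.44% of that (quartiles -12.4 and 24.4), which argues against an even background of that size. These genes were picked by their low mean over the 9 libraries, with a median of 1.20 CPM at pH 2.0. A smaller or uneven background is therefore not excluded. Total RNA per cell was not measured, so the choice between the scalings was not settled.

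Regrouping the libraries gave the number of calls under other splits. Such splits mix libraries of different pH, so their counts do not measure how many calls arise by chance. With 6 libraries the pH effect then adds to the spread within groups, which favours a count of 0. With 9 libraries mixed groups can still carry part of the pH effect. Each count of splits below includes the real split. In a fit of the 2 groups compared, 1 of 10 splits of the 6 libraries reached the real count for pH 6.0 against 2.0 (4594, highest other 0), 1 of 10 for pH 4.0 against 2.0 (3610, highest other 0) and 1 of 10 for pH 6.0 against 4.0 (3288, highest other 0); 10 splits are too few for a share under 0.05. For the lists called, 2 of 10 splits for pH 6.0 against 2.0 and 3 of 10 for pH 4.0 against 2.0 reached the real count of 1 (highest other 1 in each). For pH 6.0 against 4.0 the real count is 0, which all 10 of 10 splits reach by construction, so it says nothing of chance. For the F test, 1 of 100 drawn splits (of 280) reached 5177, the highest other being 2747. For unequal steps, 3 of 100 drawn splits (of 840) reached 3108; the highest other, 4133, kept the 3 pH groups whole with another pH in the middle, and the highest with groups not whole was 3200.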
